A study of Mus musculus with 6 samples.

How the data were processed

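RNA of 6 mouse heart samples was sequenced, 3 wild type (WT-TAC) and 3 lacking miR-204 (KO-TAC), all collected 5 weeks after transaortic constriction, a surgery that narrows the aorta and loads the left ventricle with pressure. Per the labels' protocols, RNA of high integrity went into Illumina TruSeq libraries made with either a plain or a stranded messenger RNA kit. Which kit a sample had is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. No unoperated group was analysed here, so every value compares the genotypes after surgery. Nothing in the labels says how many animals a sample came from, and p-values measure the spread between these samples.

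The deposited table holds raw counts, whole numbers per gene symbol, with no normalization by the authors. The submitters' processing notes name FastQC, HISAT2 2.1.0, Subread, edgeR, and the mouse builds mm10 and GRCm38, with no role or order. The table has 24404 genes, of which 6680 had no count in any library. All columns were used. The column of KO-TAC replicate 3 carries another number than its label does, the one that WT-TAC replicate 3 carries. It was assigned by its library index, which no other sample shares, and the leading counts are also given without it.

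Gene positions come from GENCODE M21 annotation of GRCm38. By current symbol 23350 genes matched, by an older symbol 668, and 386 had no single match. An annotated 3' UTR was found for 20100 genes, and the longest per gene was searched for seed sites.

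Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with the genotype as group and its minimum count of 10, library sizes were scaled by TMM, and a robust quasi-likelihood fit compared KO-TAC with WT-TAC with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 12487 tested genes were called changed. Fold changes are given as log2 of KO-TAC over WT-TAC, so positive values mean higher in KO-TAC. Their standard error in edgeR is the absolute log2 fold change over the square root of the test's F statistic. CPM are those of edgeR's cpm function on TMM-scaled library sizes, and log2 CPM used a prior count of 2. Intervals of fold changes span 1.96 standard errors each way, the normal multiple for 95%. They can be narrower than the quasi-likelihood test allows. For Eci1 the interval ran from 1.02 to 2.11, although the unadjusted p of that test was 0.0603.

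Gene lists for the pressure-overloaded heart, its cell types and published miR-204 targets were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested genes, 36 of them, went through camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry were alternatives.

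Genes whose 3' UTR holds AAAGGGA, the 7mer-m8 match to the miR-204-5p seed, were set against tested genes with a 3' UTR and no such site. The mature sequence was found at bases 6 to 27 of the annotated hairpin. The difference in median log2 fold change was ranked among all 35 orderings of the same bases, one-sided for higher in KO-TAC, which gives an exact p of at least 0.0286. The share of called genes within 10 Mb of Mir204 was compared with the share elsewhere by Fisher's exact test, two-sided.

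Genes named in the text are Trpm3 and Mir204, a fixed panel of 12 heart genes, the called genes with a mean log2 CPM of at least 1 whose groups do not overlap (at most 10 each way), the 3 smallest p values each way, up to 4 members of each list past its test, and called published targets. Where fewer than 5 genes passed in a direction, the 5 smallest p values are named. Predicted models, pseudogenes, Xist and Y-linked genes were left out of that choice. Some genes that the rule names are not reported here.

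Alternatives were RLE, upper-quartile and no scaling, no filter or a stricter one, DESeq2 1.42.0, limma-voom with and without quality weights, the replicate number as a block, each replicate left out, and other thresholds, windows and site classes. On data simulated for KO-TAC against WT-TAC over 12487 genes, with 100 genes changed at each fold size in 3 sets, 37.3% of genes changed 2-fold and 86.3% of those changed 4-fold were recovered, and 1 gene was called in a set with no change among 12285 tested. These sets hold no structure between libraries. In simulated fold changes of 12000 genes, a shift of 0.1 log2 in genes with the site passed in 5 of 5 sets, and no shift in 0 of 5. These fold changes were drawn independently for each gene, whereas the control orderings in the data had a median difference of −0.03. The simulation may therefore overstate what the test can detect.

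Totals ran from 6411538 to 8571737 counts. The common biological coefficient of variation was 0.286, so the spread between samples, not the depth, limits genes of moderate or high expression.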

Results

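Transcripts were counted in hearts of wild-type mice and of mice lacking miR-204, a microRNA encoded within Trpm3, 5 weeks after transaortic constriction. The series asks what this microRNA does in the hypertrophy that pressure overload brings about. Each genotype had 3 libraries. The WT-TAC libraries held 6411538, 8571737 and 7207111 counts and the KO-TAC libraries 6609315, 8494415 and 7013199. Ttn, which encodes the sarcomere protein titin, was the highest gene in each library, with 6.59% to 10.4% of all counts. Every pair of libraries differed by more than sampling noise: the median chi-square over genes with at least 50 counts was 3.01 to 7.22, against 0.455 for noise alone. Correlations of log2 CPM across genes, which are not independent replicates, ran from 0.920 to 0.960 within a genotype and from 0.905 to 0.955 between genotypes.

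The targeted gene gave no check of the labels. Mir204 lies on the plus strand of chromosome 19 from 22750605 to 22750672 (GRCm38), in an intron of all 18 Trpm3 transcripts that span it. It had 0 counts in each of the 6 libraries, wild type included. Trpm3, the host gene, from 22139046 to 22995410 on the same strand, stood at 7.76 ± 1.97 CPM in WT-TAC and 7.86 ± 1.90 in KO-TAC (SD, n = 3). Its log2 fold change was 0.02 ± 0.37 (SE), with an adjusted p of 0.999 in edgeR's quasi-likelihood test, and its deletion status cannot be read from this.

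Of all tested transcripts, 3 were called changed between the genotypes. Cacna1h, the pore-forming subunit of a T-type calcium channel, fell from 42.2 ± 14.1 CPM in WT-TAC to 4.47 ± 2.23 in KO-TAC (SD, n = 3), a log2 fold change of −3.23 ± 0.40 (SE). H2-Ea-ps, a pseudogene in the reference strain of a major histocompatibility class II chain, rose from 1 count over the WT-TAC libraries to 174 over the KO-TAC libraries, 48 to 67 in each. That ratio of rates was 178, with a 95% counting interval of 31.6 to 7079, which pools the libraries and leaves out the spread between samples. The fit gave a log2 fold change of 7.04 ± 0.87 (SE), a fold of 131 with a 95% interval of 40.1 to 430. BC002163, a processed pseudogene, rose from 5.55 ± 1.22 to 66.7 ± 30.4 CPM (SD, n = 3), a log2 fold change of 3.57 ± 0.37 (SE).

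These 3 of 12487 tested genes, 2 higher and 1 lower, passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p of 0.00865 for Cacna1h and H2-Ea-ps and 0.00585 for BC002163. The naming rule covers Cacna1h, and both pseudogenes were named after their values were seen. Cacna1h lies on chromosome 17 from 25374285 to 25433783 and H2-Ea-ps on the same chromosome from 34341959 to 34344645, a stretch described further in the closing section. BC002163 lies on chromosome 16 from 42955631 to 42955949. Over its 319 bases it is 99.4% identical to Ndufs5, a subunit of respiratory complex I that had 0 to 3 counts per library, so reads of both cannot be told apart and its level is uncertain. At an unadjusted p under 0.05 there were 170 genes higher and 196 lower in KO-TAC. DESeq2 called 16 genes, edgeR without a filter on low counts 21, and limma-voom 0 (376 at an unadjusted p under 0.05). Without WT-TAC replicate 1, 0 genes were called (437 at an unadjusted p under 0.05), without KO-TAC replicate 2, 7, and without KO-TAC replicate 3, 6. Fold changes of the called genes held with 1 library left out, at log2 values of 3.27 to 3.90 for BC002163, −3.46 to −2.87 for Cacna1h and 6.49 to 8.91 for H2-Ea-ps, and without WT-TAC replicate 1 each had an adjusted p of 0.0637. H2-Ea-ps was also not called without KO-TAC replicate 1 (adjusted p = 0.137, the highest over its alternatives, which ran from 1.52e-09).

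**Figure D1:**
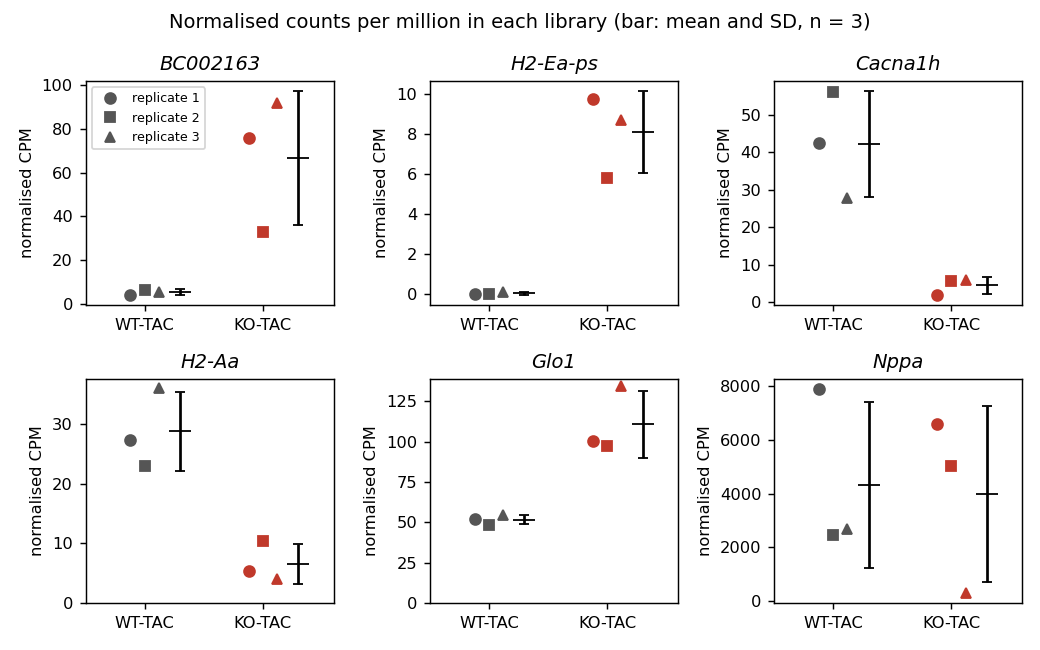
CPM scaled by TMM (vertical axes) of 6 genes in each WT-TAC and KO-TAC library. Points are libraries, with the replicate number as shape, and bars are mean and SD (n = 3). Cacna1h stands at 42.2 ± 14.1 in WT-TAC and 4.47 ± 2.23 in KO-TAC, while Nppa overlaps between the genotypes.

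The next genes by p value did not pass in edgeR with its filter on low counts. Among those lower in KO-TAC were H2-Aa (log2 fold change −2.12 ± 0.35, adjusted p = 0.102) and H2-Eb1 (−1.51 ± 0.28, adjusted p = 0.198), chains of major histocompatibility class II molecules, Ppbp (−2.46 ± 0.49, adjusted p = 0.346), a platelet chemokine, and Nr1d2 (−1.23 ± 0.25, adjusted p = 0.446), a repressor of the circadian clock. Among those higher were Glo1 (1.10 ± 0.19, adjusted p = 0.119), which detoxifies methylglyoxal, Pigyl (1.26 ± 0.27, adjusted p = 0.487), Fam124b (3.83 ± 0.85, adjusted p = 0.600), Nfil3 (1.68 ± 0.38, adjusted p = 0.600), a transcription factor of the clock, and Cep131 (1.48 ± 0.34, adjusted p = 0.607). Adjusted p values are from edgeR, and H2-Aa, H2-Eb1 and Glo1 lie on chromosome 17 near the called genes. DESeq2, and edgeR without a filter on low counts, called each of these genes except Cep131. The replicate block called Glo1 and Nr1d2, and H2-Aa was called without KO-TAC replicate 2.

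**Figure D2:**
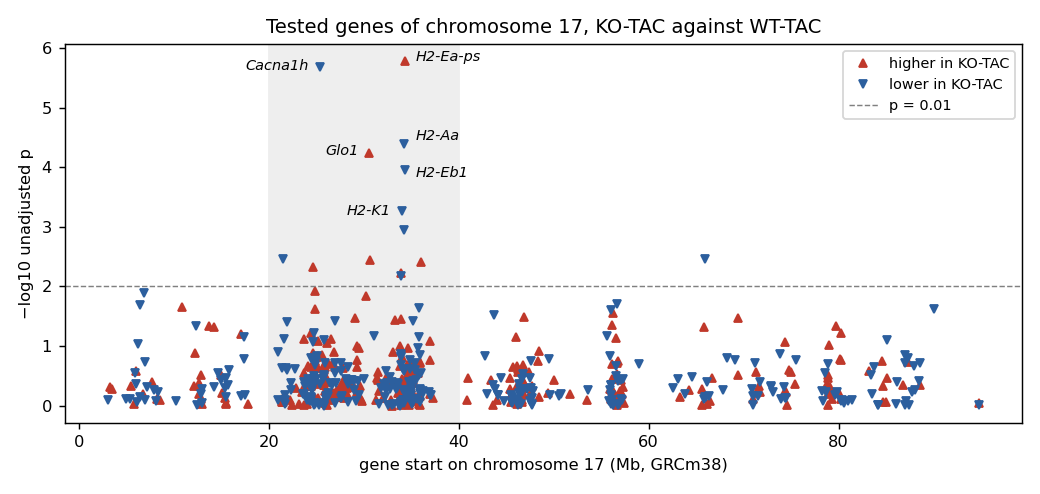
Unadjusted p (vertical axis, −log10) of each tested gene of chromosome 17 by its start (horizontal axis, Mb, GRCm38), with triangles up for genes higher in KO-TAC and down for genes lower. Of the 301 tested genes in the shaded stretch from 20 to 40 Mb, 13 had p under 0.01, the dashed line, 6 higher and 7 lower.

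No gene of the fixed panel of the hypertrophic response passed the test. Nppa, the atrial natriuretic peptide gene that pressure load induces, stood at 4338 ± 3090 CPM in WT-TAC and 3982 ± 3275 in KO-TAC (SD, n = 3), and the 95% interval of its fold change ran from 0.195 to 4.33. Nppb, the related brain natriuretic peptide gene, had a log2 fold change of 0.88 ± 0.97, Myh7, the slow myosin heavy chain of the fetal programme, 0.77 ± 0.45, and Acta1, skeletal actin, 0.55 ± 0.30. The other genes of the fixed panel had log2 fold changes of 0.10 ± 0.26 for Myh6, 0.01 ± 0.27 for Atp2a2, −0.64 ± 0.78 for Col1a1, 0.22 ± 0.58 for Col3a1, 0.69 ± 0.47 for Postn, 0.75 ± 0.92 for Ctgf (Ccn2), −0.27 ± 0.26 for Sirt1 and 0.13 ± 0.20 for Map1lc3b. All had an adjusted p of 0.999 in edgeR. With 1 library left out the log2 fold change ran from 0.10 to 1.47 for Nppb, 0.24 to 1.10 for Myh7, 0.19 to 0.84 for Acta1, 0.19 to 1.06 for Postn, 0.27 to 1.28 for Ctgf and −0.40 to −0.11 for Sirt1. KO-TAC replicate 3 had 311 CPM of Nppa and 129 of Nppb, against 6603 and 5033 of Nppa and 1492 and 817 of Nppb in the other KO-TAC libraries. WT-TAC replicate 1 had 7904 CPM of Nppa, against 2444 and 2668 in the other WT-TAC libraries.

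The hypertrophy and fetal gene list had 9 of 14 tested genes higher and 5 lower, with 0 called over all genes and 0 adjusted over the list alone. Rcan1, a calcineurin target, had a log2 fold change of 0.91 ± 0.26 (adjusted p = 0.0522 over the list) and Xirp1 0.65 ± 0.26. In camera the list had an adjusted p of 0.259. Of the extracellular matrix and fibrosis list, 26 of 34 genes were higher, 0 passed over all genes or adjusted over the list alone, and the adjusted p was 0.169. Without KO-TAC replicate 3 both lists passed camera, at adjusted p of 0.000981 with a median log2 fold change of 0.53 and 1.27e-06 with a median of 0.57, and without WT-TAC replicate 1 at 0.0318 and 0.000299. Other libraries left out turned the medians below 0. Without WT-TAC replicate 3 they were −0.062 for hypertrophy and −0.013 for fibrosis. The fibrosis median was −0.16 without KO-TAC replicate 1, and the hypertrophy median −0.20 without KO-TAC replicate 2. With all libraries both had an adjusted p of 0.886 with an estimated correlation and 0.867 in fry. With limma-voom the fibrosis list passed, and with its quality weights both did.

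Fatty acid oxidation, oxidative phosphorylation and ribosomal lists had higher medians in KO-TAC and passed camera with its preset correlation alone. Of the fatty acid oxidation genes 24 of 25 were higher, with a median log2 fold change of 0.25 (camera adjusted p = 0.00873, and 0.886 with an estimated correlation). The median was 0.0039 without WT-TAC replicate 1 and 0.0016 without KO-TAC replicate 3. Examples are Eci1 at 0.55 ± 0.27, Acads at 0.36 ± 0.19, Hadh at 0.38 ± 0.28 and Echs1 at 0.30 ± 0.20, enzymes of beta-oxidation; with 1 library left out they ran from 0.26 to 0.73, 0.23 to 0.45, 0.11 to 0.64 and 0.12 to 0.43. The nuclear-encoded oxidative phosphorylation list had 49 of 55 genes higher (median 0.12, adjusted p = 0.00696, and 0.886 with an estimated correlation), with a median of 0.013 without WT-TAC replicate 1 and 0.051 without KO-TAC replicate 3. Among them were Ndufb9 at 0.43 ± 0.21, Uqcr10 at 0.34 ± 0.20, Ndufa8 at 0.29 ± 0.19 and Ndufs6 at 0.27 ± 0.19, and with 1 library left out 0.30 to 0.56, 0.18 to 0.44, 0.17 to 0.42 and 0.13 to 0.43. Cytosolic ribosomal protein genes were higher for 29 of 39 (median 0.20, adjusted p = 0.0487, and 0.886 with an estimated correlation; median 0.066 without WT-TAC replicate 1 and 0.082 without KO-TAC replicate 1), with Rpl12 at 0.54 ± 0.27 and Rpl24 at 0.38 ± 0.22 (0.28 to 0.74 and 0.19 to 0.51 with 1 library left out). In all 3 lists 0 genes were called over all genes and 0 adjusted over the list alone.

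Smooth muscle, interferon and atrial lists had lower medians in KO-TAC and passed with the preset correlation alone. Smooth muscle markers were lower for 7 of 8 genes, with a median log2 fold change of −0.67 (camera adjusted p = 0.00376, and 0.886 with an estimated correlation), and of −0.32 without KO-TAC replicate 3 and −0.93 without KO-TAC replicate 1. They include the contractile genes Lmod1 at −1.50 ± 0.49, Tagln at −1.06 ± 0.51, Acta2 at −0.66 ± 0.34 and Myh11 at −0.62 ± 0.27, which ran from −2.17 to −1.13, −1.47 to −0.61, −0.93 to −0.31 and −0.85 to −0.32 with 1 library left out. The type I interferon response list had 12 of 18 genes lower (median −0.26, adjusted p = 0.00653, and 0.886 with an estimated correlation; median −0.21 without KO-TAC replicate 3 and −0.45 without KO-TAC replicate 1), with Ifit1 at −1.23 ± 0.38, Usp18 at −0.90 ± 0.49, Oasl2 at −0.53 ± 0.30 and Irgm1 at −0.51 ± 0.24. Leaving out 1 library gave −1.70 to −1.02 for Ifit1, −1.22 to −0.36 for Usp18 and −0.74 to −0.32 for Oasl2. All 8 tested atrial markers were lower (median −0.31, adjusted p = 0.0446, and 0.886 with an estimated correlation), but without KO-TAC replicate 3 the median turned to 0.070, and it was −0.14 without WT-TAC replicate 3 and −0.99 without KO-TAC replicate 1. Among them were Nr2f2, an atrial identity factor, at −0.72 ± 0.20, Kcnj3 at −0.57 ± 0.55, Myl7 at −0.38 ± 0.63 and Sln at −0.38 ± 0.72. In these lists 0 genes were called over all genes, and adjusted over the list alone 1 passed, Nr2f2 (0.0212). In KO-TAC replicate 3, Myl7 had 32.4 CPM, Myl4 59.0 and Sln 7.68, against 199 and 90.2, 796 and 455, and 59.9 and 33.3 in the other KO-TAC libraries. Not every atrial gene followed: Kcnj3 had 105 CPM there against 109 and 57.0, and Bmp10, removed by the filter, 4.58 against 0.146 and 0. Bmp10 also stood out in WT-TAC replicate 2, at 56.7 CPM against 0 and 0.274 in the other WT-TAC libraries.

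These 6 of 36 lists passed with a preset correlation, and 0 passed with an estimated correlation or in fry (adjusted p = 0.867 for each of the 6). Without WT-TAC replicate 1 the fatty acid oxidation, oxidative phosphorylation and ribosomal lists did not pass (adjusted p = 0.922 for each); without KO-TAC replicate 3 the ribosomal list alone of the 6 passed, with adjusted p of 0.905 for fatty acid oxidation, 0.370 for oxidative phosphorylation, 0.146 for smooth muscle, 0.267 for interferon and 0.824 for atrial markers. The ribosomal list also did not pass without KO-TAC replicate 1 (0.483) or 2 (0.294), nor the atrial list without WT-TAC replicate 3 (0.255) or KO-TAC replicate 2 (0.0903).

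**Figure D3:**
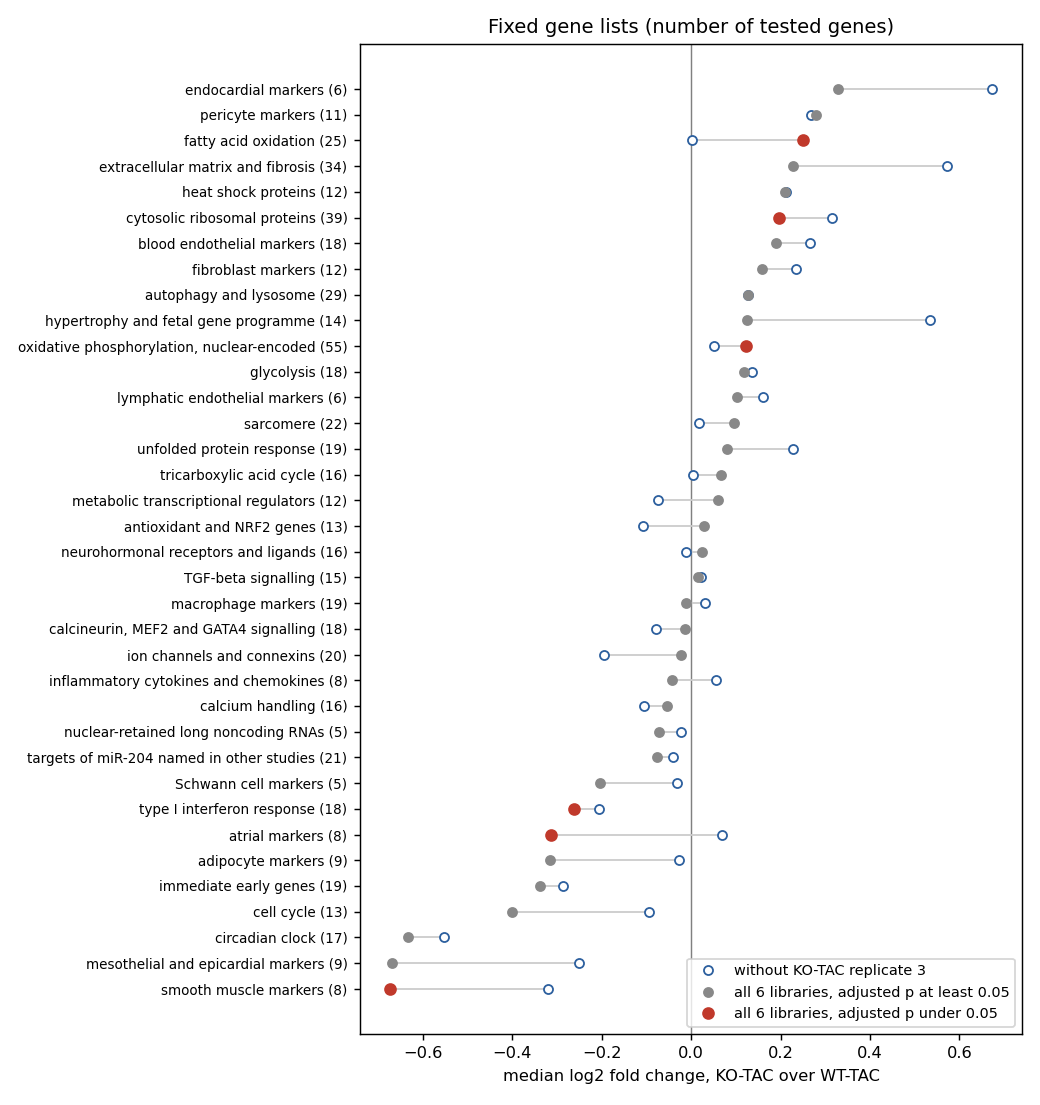
Median log2 fold change of KO-TAC over WT-TAC (horizontal axis) for the 36 tested lists (vertical axis, number of tested genes in brackets). Filled points use all 6 libraries, red where camera's adjusted p with the preset correlation was under 0.05, and open points leave out KO-TAC replicate 3. Smooth muscle markers lie at −0.67 with all libraries, and the fibrosis list moves from 0.23 to 0.57 without that library.

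Markers of other cell types did not pass camera on log2 CPM with all libraries and TMM scaling: blood endothelial (adjusted p = 0.0679), fibroblast (0.0911), pericyte (0.112), macrophage (0.298), endocardial (0.491), lymphatic endothelial (0.559), Schwann (0.524), adipocyte (0.153), and mesothelial and epicardial (0.0531) markers. Of these lists 0 members were called over all genes and 0 adjusted over the list alone. Some passed with a replicate left out: mesothelial and epicardial markers, lower in KO-TAC, without WT-TAC replicate 2 (adjusted p = 0.000418) or KO-TAC replicate 1 (0.000376), and macrophage markers, also lower, without KO-TAC replicate 1 (0.0162). Higher in KO-TAC were adipocyte markers without WT-TAC replicate 3 (1.14e-05), pericyte markers without WT-TAC replicate 2 (0.0372), and, without KO-TAC replicate 3, blood endothelial (0.00561), endocardial (0.0187) and fibroblast markers (0.0284). Fibroblast markers also passed without WT-TAC replicate 3 (0.0230) or KO-TAC replicate 2 (0.0474), and limma-voom passed the fibroblast, blood endothelial, pericyte, adipocyte and mesothelial lists, the last of which also passed with upper-quartile scaling. Too few genes were tested for T and NK cell (0), B cell (1), neutrophil (3), erythroid (3), fast skeletal muscle (3) and lung (0) markers. The mitochondrially encoded list had 0 genes in the table.

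Among heart function and stress lists, sarcomere (adjusted p = 0.564), calcium handling (0.640), ion channel (0.564), calcineurin signalling (0.888), neurohormonal (0.829), glycolysis (0.427), tricarboxylic acid cycle (0.524), metabolic regulator (0.594), TGF-beta (0.920), autophagy (0.112), unfolded protein (0.524), heat shock (0.171), antioxidant (0.916), immediate early (0.112), cytokine (0.640), cell cycle (0.270) and nuclear-retained RNA (0.888) genes did not pass camera on log2 CPM with all libraries, with 0 members called over all genes and 0 adjusted over the list alone. Immediate early and cell cycle genes passed, lower in KO-TAC, without WT-TAC replicate 3 (5.20e-05 and 0.0230) and without KO-TAC replicate 2 (0.0398 and 0.0412). Sarcomere genes passed without KO-TAC replicate 1 (0.0499), and heat shock genes in limma-voom with quality weights. For the adipocyte, calcineurin, antioxidant and TGF-beta lists the median, the mean and the test differed in sign.

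Clock genes stood apart by phase. Within the circadian list Arntl, the core activator also known as Bmal1, had a log2 fold change of 2.66 ± 0.61, Nfil3 1.68 ± 0.38 and Npas2 1.48 ± 0.50, whereas Nr1d2 had −1.23 ± 0.25 and Tef, a clock output factor, −0.92 ± 0.27. Adjusted over the list alone 3 of 17 genes were higher and 2 lower. Over all genes 0 passed in edgeR with its filter, all libraries and no replicate block, and with that block Nr1d2 was called. DESeq2 called Arntl, Nfil3 and Nr1d2 over all genes, and edgeR without a filter on low counts called Nfil3, Nr1d2 and Tef. Arntl was called without WT-TAC replicate 2, and Dbp and Per3 without KO-TAC replicate 2. Camera gave an adjusted p of 0.112 for the list, 0.000911 without KO-TAC replicate 2 and 0.886 with an estimated correlation, and the list passed in limma-voom with and without quality weights. The labels give no time of day for collection.

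**Figure D4:**
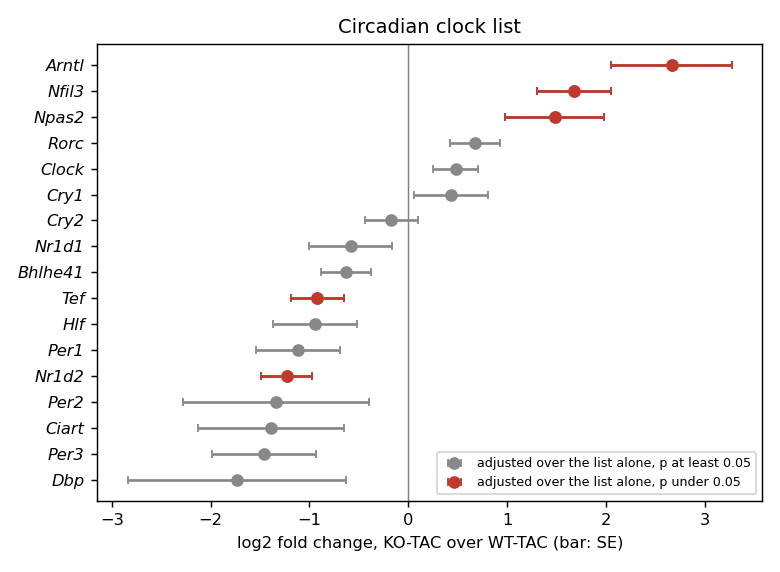
Log2 fold change of KO-TAC over WT-TAC (horizontal axis, bars are SE) for the 17 genes of the circadian clock list (vertical axis). Red points passed Benjamini-Hochberg adjustment over the list alone, from Arntl at 2.66 to Nr1d2 at −1.23.

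No rise of transcripts with a miR-204 seed site was detected in KO-TAC. The 2046 genes with AAAGGGA in the 3' UTR had a median log2 fold change of −0.02 and the 9990 without it 0.01, a difference of −0.03. Ranked among 35 orderings of the same bases, whose other differences ran from −0.04 to −0.01, this gave an exact one-sided p of 0.343. Of the published miR-204 targets 9 of 21 tested were higher and 12 lower, with 0 called over all genes, 0 adjusted over the list alone and a camera adjusted p of 0.5004. Sirt1 and Map1lc3b, both with a site, had log2 fold changes of −0.27 ± 0.26 and 0.13 ± 0.20.

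No gene around the Mir204 locus was called. Within 10 Mb of Mir204, 0 of 71 tested genes were called by edgeR, against 3 of 12340 elsewhere (Fisher's exact test, two-sided p = 1). At an unadjusted p under 0.05 there were 0 of the 71, and DESeq2 also called 0.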

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

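The alternatives were planned before the data were examined. The count of 3 called genes was kept under RLE, upper-quartile and library-size scaling, a stricter filter, removal of Xist and Y-linked genes, adjusted p under 0.10 and a fold change of at least 2, with the same 3 genes each time. It was 21 with no filter on low counts, 16 with DESeq2, 0 with limma-voom, 4 with its quality weights (H2-K1 gained), and 0 to 7 when each replicate was left out; the cause was not tested. No scaling moved the median of all genes past −0.024. The count of 6 lists became 13 with limma-voom and 11 with its quality weights, where fatty acid oxidation and oxidative phosphorylation no longer passed. It was 0 with an estimated correlation, 0 with fry and 7 with upper-quartile scaling (mesothelial gained). With library size alone, no filter and a stricter filter it was 4, and the atrial and ribosomal lists no longer passed. With a replicate left out it was 5 to 9, and the cause of these changes was not tested. Whether the replicate numbers pair the samples was not settled. Same-numbered libraries deviated from their group means with correlations of 0.135, 0.011 and 0.257, against −0.223 to 0.146 for other pairs across genotypes. Not every sample correlated best with its own number. With the replicate block 6 genes, 5 lists (atrial and ribosomal lost, fibrosis gained), a seed-site difference of −0.03 and 0 genes near Mir204 were found. The seed-site difference stayed below 0 in every setting, with p of 0.2 to 0.771 in the rank test. It was −0.06 to −0.01 with a replicate left out, and the filter at 1 CPM removed no gene. Camera in place of the rank, two-sided, gave p of 0.323 with the preset correlation and 0.0826 with an estimated one. Both went towards lower in KO-TAC. The control orderings, which camera did not use, also lay below 0 in the main fit, at −0.04 to −0.01. This direction is therefore not particular to the miR-204 site. Within 5, 10 and 20 Mb of Mir204, and with a replicate left out, 0 genes were called. Signs turned for genes that had not passed: with quality weights Col1a1 was 0.015, Nppa 0.066 and Atp2a2 −0.16, and with library size alone Atp2a2 was −0.019. With a replicate left out, the log2 fold change ranged from −0.97 to 0.046 for Kcnj3, −1.08 to 0.31 for Col1a1, −0.026 to 0.26 for Map1lc3b, −1.18 to 0.051 for Myl7, −1.08 to 0.088 for Sln, −0.040 to 0.25 for Myh6, −0.30 to 0.72 for Col3a1, −0.70 to 0.63 for Nppa, −0.13 to 0.23 for Trpm3 and −0.21 to 0.16 for Atp2a2, and the fatty acid oxidation median from 0.0016 to 0.38; the cause was not tested. Of the values of named genes, 465 kept direction and side of the threshold in settings with all libraries, 18 came to pass and 3 no longer passed; with a replicate left out these numbers were 272, 1 and 4. For the 6 lists in camera with the preset correlation, 44 values kept both and 10 no longer passed. With a replicate left out these were 24 and 11, with 1 turned in camera, fatty acid oxidation without WT-TAC replicate 1 (median 0.0039). This tally leaves out the estimated correlation and fry, in which 0 of the 6 passed. Few counts at this depth limit how closely a fold change is known, as for H2-Ea-ps with 1 count over the WT-TAC libraries.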

Other observations

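The tests of chromosome 17, of the clock genes, of the library labelled KO-TAC 3 and of platelet genes, and the bounds for the splits of the samples, were chosen after the results were seen.

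Several transcripts of platelets and their precursors had lower values in KO-TAC, and none passed the adjustment in edgeR with its filter and all libraries. Of 17 listed genes 9 were tested, all 9 had lower values in KO-TAC, 7 at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05 over all genes in edgeR. Ppbp stood at 15.0 ± 10.0 CPM in WT-TAC and 2.71 ± 0.85 in KO-TAC (SD, n = 3), Itgb3, an integrin chain, at 25.5 ± 16.7 and 6.95 ± 0.64, and Pf4, platelet factor, at 29.5 ± 19.04 and 10.6 ± 3.44. Replicate 1 carries much of this in WT-TAC: for Ppbp it had 26.6 CPM against 8.72 and 9.72, and without it the log2 fold change of −2.46 became −1.77. DESeq2 and edgeR without a filter on low counts called Itgb3 and Ppbp, and Itgb3 was called without WT-TAC replicate 3. Alox12 was level, at a log2 fold change of −0.039 ± 0.58 (SE), and Gp1ba had −1.19 ± 0.92. Alas2, an erythroid gene, was also lower, at −0.71 ± 0.30 (unadjusted p = 0.0367, adjusted p = 0.999). Because the list was written after some of these genes were seen, its test is no independent evidence.

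Small p values gathered on proximal chromosome 17: in the bin from 30 to 40 Mb, 10 of 138 tested genes had p under 0.01, and no bin outside chromosome 17 had more than 2; the Fisher p of that bin, adjusted over 216 bins, was 3.37e-06, which restates the pattern that prompted the test. The bin from 20 to 30 Mb, which holds Cacna1h, had 3 of 163 such genes and an adjusted p of 1. Fewer antigen-presenting cells are argued against as the whole cause of the lower class II genes H2-Aa, H2-Ab1 and H2-Eb1. These 3 genes fell further in KO-TAC than 16 genes of such cells elsewhere in the genome, a difference of −1.72 ± 0.41 (SE) in mean log2 CPM. They were chosen after their values were seen, and H2-DMa and H2-Ob in the same stretch had log2 fold changes of −0.82 and −0.09. The 16 genes differed by −0.07 ± 0.35 (SE), so a smaller fall of such cells is not excluded. Of the 13 genes with p under 0.01 between 20 and 40 Mb, 6 were higher in every KO-TAC library, among them H2-Ea-ps, Glo1 and Dnah8, and 7 were lower; for both sets, loss of reads of divergent alleles in alignment cannot be told apart from expression, because reads were not used here and the labels give no strains. A chromosome 17 segment from another strain stays open, since no value here decides between it and another local cause, and an effect of miR-204 on this region was not tested.

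Clock genes differed in a phase pattern. The mean log2 CPM of genes in phase with Arntl minus that of genes in the opposite phase was −2.32 to −2.06 in the WT-TAC libraries and −1.04, 0.88 and 1.16 in the KO-TAC libraries. The difference between genotypes was 2.54, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. The mean of genes in the opposite phase was 5.61 in KO-TAC 2, near WT-TAC (5.80 to 5.98), against 4.39 and 3.78 in KO-TAC 1 and 3. Between the genotypes both sets of genes moved in opposite directions (1.24 and −1.30), a pattern that could come from another time of day at collection. Loss of miR-204 acting on clock genes cannot be told apart from it, since the labels give no time of collection and 1 of the genes in phase with Arntl holds a 7mer-m8 site.

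WT-TAC 1 lay far from the other WT-TAC libraries, with r of 0.930 and 0.920 and median chi-squares of 5.59 and 6.63. What set WT-TAC 1 apart was not tested. The library labelled KO-TAC 3 likewise stood apart from the other KO-TAC libraries. A wild-type library under this label is argued against if it would resemble those of WT-TAC: at 5 of the 6 genes called without it, this library lay beyond the WT-TAC libraries on the KO-TAC side, by more than 3 SD at genes of 2 chromosomes, with 59 counts of H2-Ea-ps, where WT-TAC had at most 1, and 91.5 CPM of BC002163, where WT-TAC had at most 6.66. Over all genes it went the other way and lay closest to WT-TAC replicate 3, with r = 0.955 and a median chi-square of 3.01, the lowest of all pairs, against 0.930 and 0.937, and 5.84 and 5.96, for the other KO-TAC libraries, so its genotype at Mir204 stays unread. Its atrial markers had a median log2 ratio of −2.27 to the other KO-TAC libraries, below all of 10000 random lists matched on expression. Less atrial tissue may be a cause, although Kcnj3 lay between the other KO-TAC libraries. Nr2f2 was nearly level, at 26.2 CPM against 30.5 and 28.2. Bmp10, removed by the filter and not in that median, lay above both, at 4.58 CPM against 0.146 and 0. The hypertrophy list without its atrial genes had a median of −0.91, also below all 10000 random lists, so a weaker response to the surgery in this sample stays open as well. Fibrosis genes had a median of −1.34, again below all 10000, and sarcomere genes 0.02. The random lists were drawn gene by gene, so any list whose genes move together can fall below them. These ranks therefore do not choose between the causes.

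Splits of the 6 libraries into 3 against 3 number 10, too few for a share under 0.05. The genotype split called 3 genes and the highest other split 90, and 2 of the 10 called at least 3. That other split set WT-TAC 1, KO-TAC 1 and KO-TAC 2 against the rest, so the libraries hold a structure that crosses genotype. For gene lists the genotype split gave 6 and the highest other 12, with 9 of the 10 splits at 6 or more. For seed sites the genotype split gave an exact p of 0.343 in the rank test and the lowest other 0.0286, with 9 of the 10 at or below the genotype split. In each split this one-sided test looked for higher values in the group without WT-TAC 1. For splits other than the genotype split that direction is arbitrary, and the count depends on it.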
